A study of Mus musculus with 16 samples.

How the data were processed

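Libraries of polyA RNA were made with the Illumina TruSeq kit from tumour RNA, per the labels' protocols. The submitters' processing notes name the mm9 genome build, RSEM 1.2.12 and Bowtie 1.0.1, without giving their roles; the annotation, filters and strandedness are not given in the sources used here. The authors deposited estimated counts per gene, as RSEM gives them, which are not whole numbers and are not normalized. The authors also deposited a normalized table, a signal made of the same estimated counts divided by a single factor per library, as the values show; how the factor was derived is not given in the sources used here. The count table held 23224 genes and the normalized file held 22484, so 740 were listed in the former alone. Among the count rows, 25 gene symbols had turned into dates; these rows stayed in the tests and are not named. Every sample column was matched to a sample by its title, and 0 columns belonged to no sample.

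Estimated counts were rounded to whole numbers and analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were kept by filterByExpr with the groups, which left 16084, and libraries were scaled by TMM. A single quasi-likelihood fit (glmQLFit and glmQLFTest) held all 3 groups, each test group was compared with the B6 controls, and p-values were adjusted by Benjamini and Hochberg over all genes tested, with a threshold of 0.05. Standard errors of log2 fold changes were taken as the fold change over the square root of F. Levels are given as CPM, counts per 1e+06 counts of the TMM-scaled library, and log2 CPM used a prior count of 2. Before the data were examined, 30 gene lists were fixed, of which 28 were tested with camera at a preset correlation of 0.01, with an estimated correlation and fry as alternatives. Depth was similar across libraries (38561334 to 57013815 estimated counts), and genes with few counts carry wide errors.

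The genes named were set by a rule fixed before the data were examined. It takes Dlgap1, Fmr1, Hsf1, the Grin1 and Grin2 genes and the vesicular glutamate transporters whatever their p; the 10 largest rises and 10 largest falls past the threshold with a mean log2 CPM of at least 1 and every test library on the same side of the control mean; up to 4 members with the smallest p in each list described; and strain and sex control genes. Grin2a was below the expression filter.

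Replicates of a group differed by more than sampling noise, with a chi-square per degree of freedom of at least 116.6 between any 2 libraries of a group, so none was treated as a library deposited again. This does not show that the libraries came from separate tumours, since repeat preparations of a tumour can also differ by more than sampling noise. Counts were simulated from the real means, dispersions and library sizes, with 200 changed genes picked among those with a mean log2 CPM of at least 1. On these counts the same steps recovered 29% of genes changed by log2 1 and 80% of those changed by log2 2 in the strain comparison. In the MK801 comparison they recovered 39% and 84%, with 3 false calls in each comparison among 15906 and 15909 genes. Recovery of changes in genes with lower levels was not tested. These counts vary independently between genes, without the gene-gene correlation of the real libraries, and recovery under such correlation was not tested.

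Alternatives planned before the data were examined were DESeq2 1.42.0 size factors and its Wald test, upper-quartile factors, limma-voom, limma on the log2 of the authors' normalized values plus 1, other low-count filters, fits of the 2 compared groups alone, the replicate number as a block, stricter thresholds, acinar genes removed or as a covariate, a Y-linked covariate, a first surrogate variable from sva 3.50.0, and leaving out each library. Alternatives added after seeing the data were a covariate for the GC trend, alone and with the replicate block, the 3 libraries with the steepest GC trend left out, and a leukocyte score covariate (the mean of the macrophage and T and NK list scores). GC content came from the longest GENCODE M21 transcript of each symbol on GRCm38, a different build from that of the files, and was found for 98.4% of the genes tested; gene order came from the GRCm38 gene table, and no coordinates are given.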

Results

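The series profiled polyA RNA from pancreatic neuroendocrine tumours of RIP1Tag2 mice, in which the SV40 T antigens are expressed from the rat insulin promoter and beta cells become tumours. All tumours came from mice of 14 to 16 weeks. The 16 libraries fell into 3 groups: 7 from the C57Bl/6 background (B6 controls, untreated or given saline), 4 from the C3HeB/Fe background (C3H controls) and 5 from B6 mice given MK801, an antagonist of the NMDA receptor, at 1 mg/kg daily for 3 days. Estimated counts summed to 38561334 to 57013815 per library. Insulin transcripts took 1.23% to 8.85% of each library's counts, and digestive enzyme genes of acinar cells took 0.00358% to 6.93%, with a wide range inside each group. The labels do not say that each library came from a separate mouse, so p-values measure the spread between these samples, which may in part be technical.

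The leading axis of variation among the libraries went with base composition and not with the groups. The first principal component held 30.4% of the variance, and its gene loadings correlated with transcript GC content across genes, which are not independent replicates (absolute Spearman rho = 0.592). A GC trend was computed for each library as the rank correlation across genes between its log2 deviations and GC content. The GC trend averaged -0.046 ± 0.38 (SD, n = 7) in B6 controls, 0.14 ± 0.31 (SD, n = 4) in C3H controls and -0.086 ± 0.20 (SD, n = 5) after MK801. Over the 16 libraries it correlated with the first component (Pearson r = 0.957 and Spearman rho = 0.953, permutation p = 1e-05 for each, the smallest that 100000 permutations can give), and without the 2 libraries farthest from the median GC trend r was 0.935. Both measures come from the same expression values. This relation was noticed in the data and was not planned. Base composition was not separated from other differences between the libraries. At the high end of this component, the list of secretory granule and exocytosis genes averaged 8.161 log2 CPM in B6 control replicate 5 and 8.071 in C3H replicate 1. At the low end it averaged 7.052 and 7.064 in B6 control replicates 6 and 7. The second component held 16.5% of the variance and followed the groups. Its scores ran from -84.34 to -33.14 in C3H controls, from -39.92 to 22.93 in B6 controls and from 26.11 to 67.24 after MK801.

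**Figure D1:**
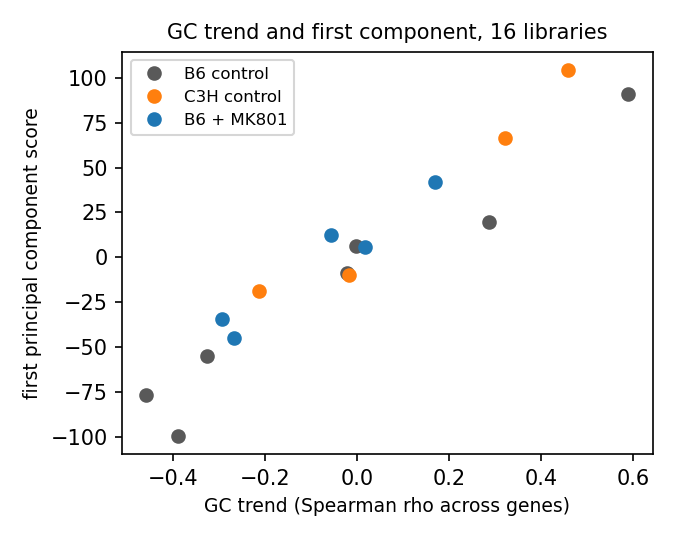
Each point is a library, with its GC trend (Spearman rho across genes, no unit) on the x axis and its first principal component score on the y axis, coloured by group. Libraries of all 3 groups are spread along the same line (r = 0.957).

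The first comparison asked how tumours of the C3H background differed from those of the B6 background; the title of the series names GKAP, the product of Dlgap1, as a genetic modulator of NMDA receptor signalling. Dlgap1, which encodes a scaffold protein that links the PSD-95 and Shank proteins beneath the NMDA receptor, was nearly absent from C3H tumours. It stood at 29.8 ± 5.70 CPM (SD, n = 7) in B6 controls and 0.535 ± 0.354 CPM (SD, n = 4) in C3H controls, a log2 fold change of -5.78 with a standard error of 0.416 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 5.3e-07). The call held in all 34 alternatives run for this gene, with log2 fold changes from -6.24 to -5.52 and adjusted p-values of at most 0.0193. After MK801 Dlgap1 stood at 33.7 ± 6.61 CPM (SD, n = 5), with an edgeR adjusted p of 0.916 against B6 controls.

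**Figure D2:**
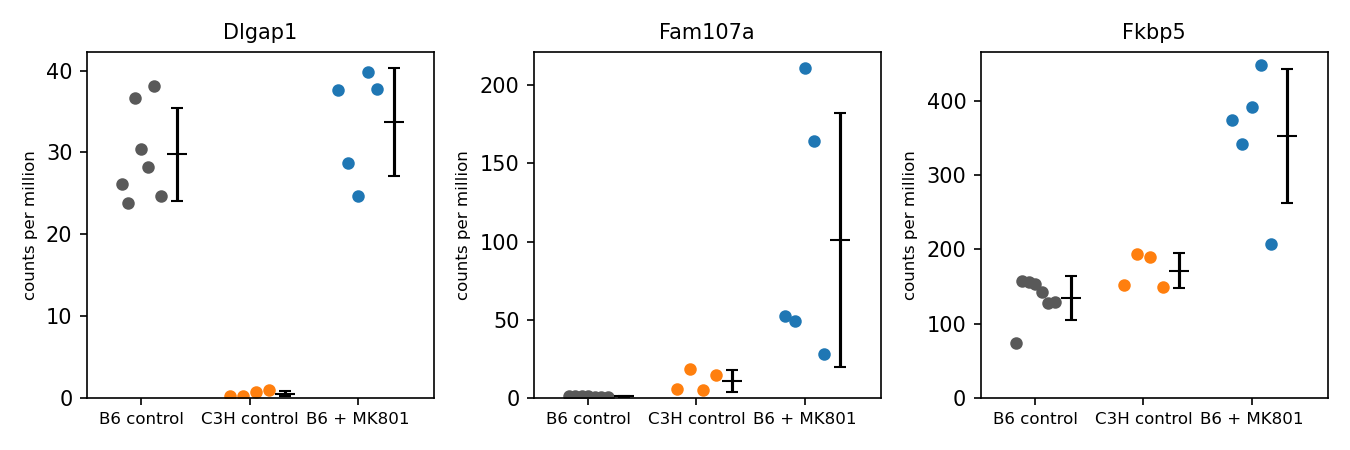
CPM of Dlgap1, Fam107a and Fkbp5 on linear axes, 1 point per library, with the mean and SD of each group as a black bar beside the points. Dlgap1 lay near 0 in C3H tumours (mean 0.535 CPM), and Fkbp5 was highest after MK801 (mean 353 CPM).

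Of 16084 genes tested, 142 were higher and 244 were lower in C3H tumours. Among the other genes of the receptor pathway, Grin1, the obligatory receptor subunit, stood at 25.1 ± 32.3 CPM in B6 and 43.2 ± 32.1 CPM in C3H tumours (edgeR adjusted p = 0.701). Grin2b, Grin2c, Grin2d and the vesicular glutamate transporters Slc17a6, Slc17a7 and Slc17a8 did not pass the test either, and Grin2b and Grin2d were under 1 CPM on average in both strains. Slc17a6 and Grin2c had large but imprecise log2 fold changes of 2.74 and 1.89, with standard errors of 1.07 and 1.28. Fmr1, which encodes an RNA-binding protein of neurons, had a log2 fold change of -0.26 (edgeR adjusted p = 0.605), and Hsf1, the heat shock transcription factor, one of 0.43 (edgeR adjusted p = 0.558). Of the 33 tested members of the NMDA receptor and scaffold list, Dlgap1 fell and the others did not pass the test. Next by p were Dlgap2, Camk2b and Dlg2, with log2 fold changes of -2.30, 0.62 and -2.18 (edgeR adjusted p = 0.189, 0.19 and 0.237). The list's median log2 fold change was 0.16 and its mean -0.12 (camera adjusted p = 0.882). Failing the test does not show that these genes were unchanged. With the GC trend of the libraries as a covariate, added after seeing the data, 192 genes were higher and 259 lower. The count of lower genes was 152, 112, 104 and 142 without C3H replicates 1, 2, 3 and 4.

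The largest rise among the genes chosen by size was that of Pyy, the gut and islet hormone peptide YY, at 2.44 ± 1.69 CPM in B6 and 447 ± 580.5 CPM in C3H tumours (log2 fold change 7.51, edgeR adjusted p = 0.000476). Cish, a feedback inhibitor of cytokine receptor signalling, rose from 6.59 ± 2.88 to 44.6 ± 15.5 CPM (edgeR adjusted p = 0.000156). Fam107a, an actin-associated stress-response gene, rose by a log2 fold change of 3.54 (edgeR adjusted p = 0.00102). The adenosine receptor gene Adora1, the membrane protease gene St14, Pyroxd2, Calml4, Gchfr and Ppp1r3b also rose, with log2 fold changes from 2.17 for Ppp1r3b to 3.13 for St14. Single libraries set much of the mean for some: St14 had an SD of 44.1 CPM around a C3H mean of 34.6 CPM. Pyy was at 1302 CPM in C3H replicate 1 and at 84.35 to 316.9 CPM in the other C3H libraries. Its call held whichever C3H library was left out (edgeR adjusted p of at most 0.00156). St14, Calml4 and Gchfr lost their calls without C3H replicate 1, with edgeR adjusted p-values of 0.141, 0.104 and 0.104, and Adora1 lost its call without C3H replicate 2 or 3, with edgeR adjusted p-values of up to 0.0781.

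Folr1, a folate receptor gene, fell from 52.0 ± 33.7 to 1.31 ± 0.605 CPM (log2 fold change -5.31, edgeR adjusted p = 5.75e-05). Adamdec1, a metalloprotease gene, had at most 3 counts in any C3H library and 8.32 ± 3.97 CPM in B6 tumours (edgeR adjusted p = 0.000156). The peptide transporter gene Slc15a2, C1ql3, S100z, Col6a6, Prdm16 and C8b fell as well, with log2 fold changes from -6.69 for Slc15a2 to -3.67 for C8b. Slc15a2, C1ql3, Prdm16 and C8b lost their calls whichever of the 4 C3H libraries was left out, with edgeR adjusted p-values from 0.0591 for Slc15a2 to 0.133 for C1ql3. Col6a6 lost its call without C3H replicate 1, 2 or 4 and S100z without replicate 2, 3 or 4, with edgeR adjusted p-values of up to 0.108 and 0.0759. The level of C1ql3 was 124.9 CPM in B6 control replicate 1 and 1.80 to 12.6 CPM in the other B6 controls. Slc15a2 stood at 50.38, 66.2 and 67.64 CPM in B6 control replicates 1, 3 and 4. In the other B6 controls it was at 0.7395 to 3.994 CPM, and in C3H libraries at 0.08976 to 0.5417 CPM. Dynlt1a fell by 4.57 on the log2 scale, but it has near-identical copies among which reads may be split, so its level is uncertain.

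Genes with known differences among these strains served as a check of the labels. H2-Ea-ps, the transcript of a class II gene with a promoter deletion in B6 mice, had at most 4 counts in any B6 control and 34.2 ± 6.90 CPM in C3H tumours. Sp110 fell by 2.65 on the log2 scale (edgeR adjusted p = 0.000425) and Glo1 rose by 1.10 (edgeR adjusted p = 0.000194). Nnt and Pde6b did not pass the test (edgeR adjusted p = 0.751 and 0.407). Y-linked transcripts were present in both strains, with Ddx3y at 119.5 ± 24.8 CPM in B6 and 152 ± 43.9 CPM in C3H tumours.

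Among the 28 gene lists tested, camera with a preset correlation called 7 in the strain comparison, 5 of them lower in C3H. In the mitosis list 7 of 23 members fell and none rose, and 21 fell when adjusted over the list alone. Kif20a, a mitotic kinesin, fell from 148 ± 41.7 to 75.7 ± 12.4 CPM, and Bub1b and Cenpe, which act at kinetochores, fell by 1.00 and 1.07 on the log2 scale. All 3 genes lost their calls without C3H replicate 1, 2 or 3, with edgeR adjusted p-values of up to 0.119. The camera adjusted p of this list was 1.18e-19, but the adjusted p = 0.688 with an estimated correlation did not pass. In the interferon list 1 of 29 members, Ifi44, rose (log2 fold change 1.88), and 13 rose when adjusted over the list alone (camera adjusted p = 4.25e-12, against an adjusted p = 0.919 with an estimated correlation). Ifi44 lost its call without C3H replicate 2 or 3 (edgeR adjusted p of up to 0.22). In the antigen presentation list 2 of 23 members rose, H2-Ea-ps and H2-T23, and the same 2-gene count was found when adjusted over the list alone (camera adjusted p = 0.000482, against an adjusted p = 0.919 with an estimated correlation). H2-T23 and H2-K2, which rose to 35.8 ± 2.84 CPM in C3H tumours, belong to a family of similar genes whose strain variants can move reads between members, so their levels are uncertain. The DNA replication, other glutamate and GABA receptor, macrophage and oxidative phosphorylation lists were called lower, with 0, 0, 1 and 1 members that fell, and each had an adjusted p = 0.919 with an estimated correlation. The macrophage member was Fcer1g, which lost its call whichever C3H library was left out, and the oxidative phosphorylation member Sdhc, which lost it without C3H replicate 2, 3 or 4 (edgeR adjusted p of up to 0.154 and 0.0992). With an estimated correlation none of the 7 lists passed (adjusted p from 0.688 to 0.919), and fry called 0 of the 28 lists, with 3 at an unadjusted p under 0.05. The other 21 lists had camera adjusted p-values from 0.0647 to 0.981, the beta cell list being the lowest.

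**Figure D3:**
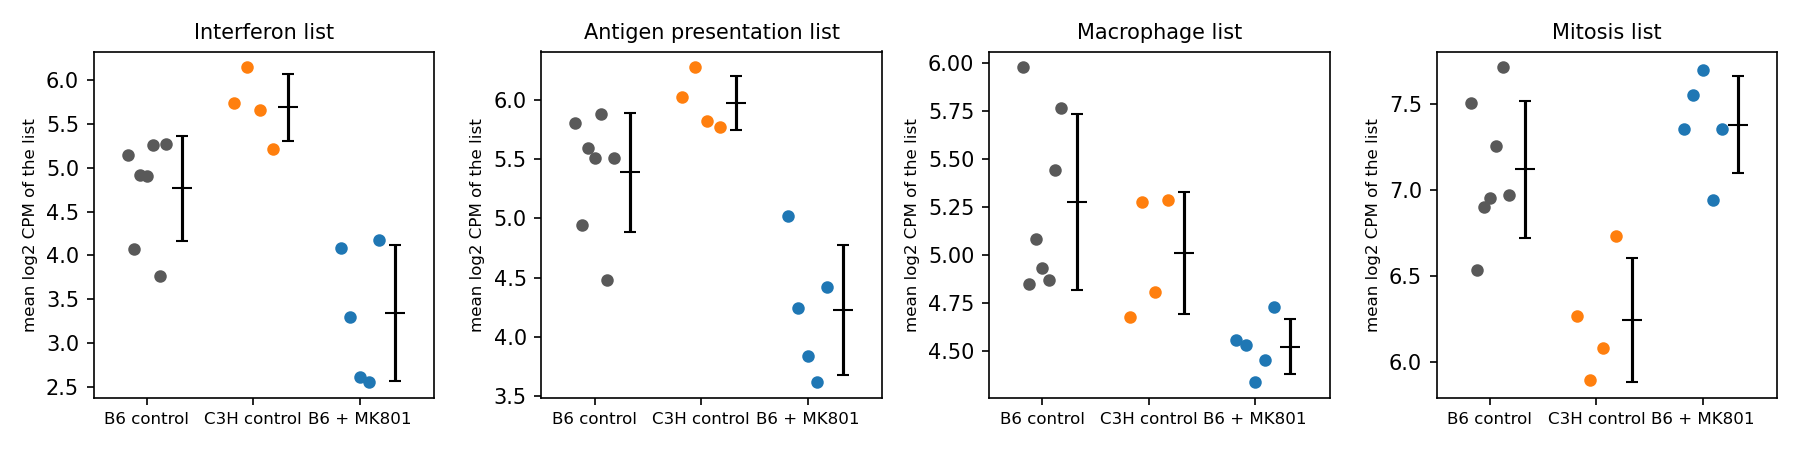
Mean log2 CPM over the genes of 4 lists, 1 point per library, with the mean and SD of each group as a black bar; the y axes do not start at 0. The interferon and antigen presentation scores were lowest on average after MK801, and the mitosis score was lowest on average in C3H tumours.

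The second comparison asked what 3 days of MK801 changed in B6 tumours. The labels do not say which control libraries came from untreated and which from saline-treated mice, nor the sex of the mice or the time of sampling, so a difference from MK801 cannot be separated here from one of injection and handling. Of 16084 genes, 24 were higher and 76 were lower, with Fam107a and Fkbp5 among the higher ones. In the antigen presentation list 6 of 23 members fell and in the interferon list 2 of 29. Each list had an adjusted p = 0.0604 with an estimated correlation, while the fry adjusted p was 0.00947 and 0.00957.

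Fam107a rose from 0.936 ± 0.298 to 101 ± 81.4 CPM (SD, n = 7 and 5; log2 fold change 6.75, edgeR adjusted p = 4.46e-05). Fkbp5, a chaperone of the glucocorticoid receptor and itself a hormone-responsive gene, rose from 134.5 ± 29.3 to 353 ± 89.7 CPM (edgeR adjusted p = 0.00928). Mdm1 rose from 195 ± 19.6 to 503 ± 139 CPM (edgeR adjusted p = 0.00686), and Gpd1, a glycerol phosphate dehydrogenase gene, from 12.7 ± 4.02 to 46.8 ± 20.9 CPM (edgeR adjusted p = 0.00928). Reln, Ankrd6, Mtus1, C1qtnf6, the DNA repair gene Brca2 and the clock gene Cry2 rose by log2 fold changes of 1.05 for Cry2 to 2.30 for Reln. Cry2 lost its call whichever of the 5 MK801 libraries was left out, with edgeR adjusted p-values from 0.0568 to 0.121. Ankrd6 and Mtus1 lost theirs without MK801 replicate 1, 2, 3 or 4, and Reln, C1qtnf6 and Brca2 without replicate 2, 3 or 4, with edgeR adjusted p-values of up to 0.159. Fkbp5 and Gpd1 each had an edgeR adjusted p of 0.051 without MK801 replicate 4, while Fam107a and Mdm1 passed without each MK801 library.

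Of the antigen presentation list none rose, and 15 members fell when adjusted over the list alone. H2-Ab1 fell from 97.5 ± 35.0 to 19.2 ± 14.1 CPM (edgeR adjusted p = 0.0216), and H2-Eb1 fell from 122 ± 51.9 to 22.4 ± 16.9 CPM (edgeR adjusted p = 0.0233). H2-Aa and Cd74, the invariant chain, fell by 2.25 and 2.16 on the log2 scale, and H2-DMb1 by 1.47. The interferon members that fell were the nucleic acid sensor gene Zbp1 and Ifi27l2a, by 2.27 and 2.25 on the log2 scale. All of these named genes lost their calls without MK801 replicate 2, 3 or 4, with edgeR adjusted p-values of up to 0.122. Of that list 24 members fell when adjusted over the list alone, and its median log2 fold change was -1.35. The camera adjusted p was 1.43e-33 for the interferon and 1.09e-22 for the antigen presentation list, against an adjusted p = 0.0604 with an estimated correlation for each. The fry adjusted p was 0.00957 and 0.00947, so the 2 alternatives differed.

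Among the lists of other cell types, the macrophage, T and NK cell, B and plasma cell, and mural cell and fibroblast lists had median log2 fold changes of -0.72, -1.44, -1.32 and -0.98, with 0 members called by edgeR in each over all genes. Each of these lists had an adjusted p = 0.0604 with an estimated correlation and a fry adjusted p of 0.00947. Adjusted over the list alone, 12 of 19, 13 of 19, 6 of 14 and 11 of 21 members fell. The macrophage gene C1qb stood at 192.5 ± 35.9 CPM in controls and 117 ± 23.9 CPM after MK801 (edgeR adjusted p = 0.0533). The endothelial and neutrophil lists were called lower by camera (adjusted p = 0.00382 and 0.0157). With an estimated correlation the adjusted p was 0.628 and 0.396, and with fry it was 0.344 and 0.101. Slfn1, Clec4a1, Clec12a and Ccl2, genes of immune cells and their recruitment, fell by 2.69, 2.57, 2.30 and 2.19 on the log2 scale. The secreted factor gene Wisp2 fell by 2.19 (log2 fold change -2.19, edgeR adjusted p = 0.0303). Clec4a1 lost its call whichever MK801 library was left out (edgeR adjusted p from 0.0607 to 0.122), Clec12a without MK801 replicate 1, 2, 3 or 4 (up to 0.105), Wisp2 without replicate 2, 3 or 4 (up to 0.0702), and Slfn1 and Ccl2 without replicate 2 or 4 (up to 0.0935 and 0.0591).

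In the list of invasion proteases 1 of 27 members, Ctsh, which encodes cathepsin H, fell from 83.6 ± 19.5 to 47.2 ± 8.83 CPM (edgeR adjusted p = 0.0427), and 7 fell when adjusted over the list alone. Ctsh lost its call without MK801 replicate 1, 2, 3 or 4 (edgeR adjusted p of up to 0.123). The list's camera adjusted p was 1.87e-06, against an adjusted p = 0.243 with an estimated correlation and 0.0586 with fry. The mitosis list was called higher by camera (adjusted p = 0.000399) with 0 members called. The adjusted p was 0.730 with an estimated correlation and 0.538 with fry. The other 18 lists, among them the NMDA receptor and scaffold, heat shock, immediate early and beta cell lists, had camera adjusted p-values from 0.0773 to 0.922. Fmr1, Hsf1, Grin1 and the other named receptor and transporter genes did not pass the test after MK801, with edgeR adjusted p-values from 0.658 for Slc17a8 to 0.997 for Grin2c. The Y-linked genes and Xist, which mark the sex of the mice, had higher averages after MK801 and did not pass the test. Over all libraries Ddx3y ran from 91.19 to 319.2 CPM, Kdm5d from 29.35 to 110.3 CPM and Uty from 23.18 to 107.2 CPM. No library lacked these transcripts, which argues against a library made of female tissue alone in any group. Ddx3y stood at 119.5 ± 24.8 CPM in B6 controls and 175.7 ± 84.3 CPM after MK801 (log2 fold change 0.56, unadjusted p = 0.0425, edgeR adjusted p = 0.393), and Kdm5d, Eif2s3y and Uty had log2 fold changes of 0.50, 0.97 and 0.45 (edgeR adjusted p = 0.395, 0.577 and 0.56). Eif2s3y was at 3.64 and 8.04 CPM in B6 control replicates 4 and 5 and at 47.0 to 108.6 CPM in the other B6 controls, and its log2 fold change was 0.76 and 0.78 without each of these 2 libraries. Xist stood at 1.57 ± 0.801 and 4.58 ± 5.64 CPM (log2 fold change 1.54, unadjusted p = 0.0323, edgeR adjusted p = 0.351). B6 MK801 replicate 4 had the highest levels, at 319 CPM of Ddx3y and 14.2 CPM of Xist, and without it the log2 fold changes of Ddx3y and Xist were 0.18 and 0.41. None of the 23 named genes called after MK801 was called under every alternative. The leukocyte score covariate, under which edgeR called 0 genes, fixed this result, so it does not tell how stable each gene was. The numbers of genes called fell to 2 higher and 2 lower without B6 MK801 replicate 4 and rose to 37 and 165 without B6 MK801 replicate 5. With the GC trend of the libraries as a covariate, added after seeing the data, 121 genes were higher and 266 lower. With a leukocyte score as a covariate edgeR called 0 and 0, with 363 and 207 at an unadjusted p under 0.05. Together these are fewer than 0.05 of the 16084 genes tested, the share that chance alone would give. But the macrophage and T and NK scores averaged 5.27 and 0.162 log2 CPM in B6 controls and 4.52 and -1.24 after MK801. The covariate thus follows the groups and takes up part of their difference, and genes are correlated. These counts therefore cannot show that nothing beyond leukocytes changed. A covariate for Y-linked transcripts left 1 higher and 1 lower gene, and a fit of the 2 compared groups alone 7 and 3.

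The last comparison set the strain and MK801 changes side by side. Across the 16084 genes the fold changes had a Pearson r of 0.15 and a covariance of 0.059, and genes are not independent replicates. The jackknife standard error of r over the 16 libraries was 0.244. Both comparisons share the B6 controls, and simulated unchanged groups against those controls gave a median r of 0.39 and a median covariance of 0.089 over 100 simulations. The simulated counts vary independently between genes, without the GC trend of the real libraries. Given the standard error, they cannot show that the observed r lies below that of unchanged groups. With the 7 controls divided 3 and 4 between the comparisons, the median r over 70 assignments was -0.06, from -0.344 to 0.15. In both lists of higher genes 1 gene, Fam107a, was found, where independent lists would share 0.212. Of lower genes 1, Mnda, was in both, where independent lists would share 1.15. These expected overlaps ignore the shared controls, and none that allows for them was computed. Cish was called in opposite directions, higher in C3H and lower after MK801. These last 2 genes were named after their values were seen.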

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

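The tests with covariates for leukocytes and GC trend were chosen after the result was seen; the other tests were written before it, but the reading of the test of linked blocks was made more cautious afterwards, as told beside it. Regrouping the samples at random was planned.

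Chance as the source of the counts was weighed by refitting 100 splits of the same samples, the real one included. In the strain comparison 5 splits gave at least the 142 higher genes and 3 gave at least the 244 lower genes. The lower count met the criterion set beforehand, fewer than 5 of 100 splits, and the higher count did not. Other splits also reached the lower count, so chance is not excluded for either. The highest of the other splits gave 1491 and 933. That split called many times more genes than the real one, which points to a structure of the samples: it had the largest difference in mean GC trend of the 100 splits, 0.617 against 0.183 for the real split. The 4 other splits with as many higher genes differed by 0.421 to 0.617, but of the 10 splits that differed by at least 0.421 edgeR called 0 higher and 0 lower genes in 6, so the size of this difference alone did not set the counts. In the MK801 comparison 2 splits gave at least the 24 higher genes (highest other 39) and 1, the real split, gave at least the 76 lower genes (highest other 1). Both counts met the same criterion. Counts this large were rare among the splits drawn, but 100 splits do not exclude chance. For the lists called with a preset correlation chance was not excluded: 76 of 100 splits gave at least the 7 lists of the strain comparison and 62 at least the 10 lists of the MK801 comparison, with up to 17 in another split of each.

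After MK801 2 of 29 interferon and 6 of 23 antigen presentation genes fell. Each list had an adjusted p = 0.0604 with an estimated correlation, and the fry adjusted p was 0.00957 and 0.00947. The median log2 fold change of the interferon list was -1.35. A GC trend of the libraries was argued against, since with it as a covariate the median was -1.324 and lay between -1.51 and -1.21 when each library was left out. The antigen presentation median was -1.032 without this covariate and -0.9407 with it. Fewer leukocytes in the samples stay open: with the leukocyte score as a covariate the interferon median shrank to -0.3632, from -0.618 to -0.164 without each library, and 26 of 29 members stayed below 0. The antigen presentation median shrank less, from -1.032 to -0.5499. Leukocytes express many of these genes themselves, so the covariate may also remove a change within them, and a change caused by MK801 stays open too.

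The genes that differ between strains, Dlgap1 among them, formed 26 neighbouring pairs in gene order, against a mean of 8.84 in random sets (permutation p = 1e-04, the smallest that 10000 permutations can give). Linked chromosome blocks may account for this, but the genes called after MK801, within a single strain, formed 7 pairs against 0.619, so clustered gene families cannot be told apart from blocks; that comparison was added after the first value was seen. A change spanning Dlgap1 and its neighbours on both sides was argued against: the nearest 10 tested genes had a median log2 fold change of -0.0397, and 0 of them passed the test. Those on one side had log2 fold changes of 0.0197 to 0.464 and those on the other -0.9485 to -0.0991. The pooled median therefore cannot weigh a smaller change on a single side. Whether C3H variants lowered the alignment of Dlgap1 reads to the reference was not tested.

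Of 315 groups of values examined for a library far from the others, 27 held such a library, where chance gives about 1 in 20. The ratios below are its gap to the nearest other library over the range of the group. C3H replicate 1 stood apart for the other islet hormone list (0.852), Fmr1 (0.84), Slc17a8 (0.858) and St14 (0.859). B6 control replicate 1 was low for the beta cell list (0.717), Fkbp5 (0.728) and Egln3 (0.646). B6 control replicate 7 stood apart for the adipocyte list (0.659), Prdm16 (0.62) and C1qtnf6 (0.636). B6 control replicate 5 did so for Grin2d (0.648) and Brca2 (0.596), replicate 6 for Pyroxd2 (0.685), and replicate 2 for its total estimated count of 38615267 (0.692) and Kdm5d (0.65). B6 MK801 replicate 5 stood apart for the mural cell and fibroblast list (0.853), Adamdec1 (0.847) and Slc15a2 (0.786). B6 MK801 replicate 4 was high for Gpd1 (0.775) and Eif2s3y (0.731) and low for Ctsh (0.725), replicate 2 was high for Ankrd6 (0.789), and replicate 3 was low for Slfn1 (0.781) and high for Ccl2 (0.731). C3H replicate 3 was low for Clec12a (0.921) and C3H replicate 2 high for Ccl2 (0.903) and Sp110 (0.947).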

How the results depend on the processing

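The GC trend and leukocyte settings were chosen after seeing the data. No pairing by replicate number was seen. In their deviations from group means, same-numbered libraries correlated from -0.312 to -0.00158 in the strain and from -0.164 to 0.114 in the MK801 comparison. None correlated best with its own number. This check took all genes together, so a weaker pairing is not excluded. With the replicate block the counts were 65 higher and 97 lower in C3H, and 1 higher and 0 lower after MK801. At an unadjusted p under 0.05 edgeR gave 750 and 1288 after MK801 with the block, against 563 and 1367 without it. The replicate block on the 2 groups with shared numbers gave 21 and 13, and 1 and 0, and the block with the GC trend covariate 82 and 116, and 29 and 196. Counts that moved by more than 1.5 times are given as higher and lower. For the strain comparison they were 65 and 156 with the stricter filter, 290 and 546 with DESeq2, 92 and 129 without the 3 libraries of steepest GC trend and 67 and 86 at an adjusted p under 0.01; 238 higher with the surrogate variable; and 129 lower with only the 2 groups. For MK801 they were 13 and 47 with the stricter filter, 109 and 575 with DESeq2, 7 and 3 with only the 2 groups, 1 and 1 with the Y-linked covariate, 121 and 266 with the GC trend covariate, 6 and 4 without the steep libraries, 0 and 0 with the leukocyte covariate (363 and 207 at an unadjusted p under 0.05) and 6 and 2 at an adjusted p under 0.01; 42 higher with the surrogate variable; and 46 lower without a filter, 157 with the authors' normalized values and 48 with the acinar covariate. The unadjusted 363 and 207 with the leukocyte covariate are together fewer than chance alone would give. The leukocyte score itself differed between the groups, so the covariate takes up part of the group difference. These counts cannot show that nothing else changed. The stricter filter tests fewer genes and leaving out libraries uses fewer samples. Otherwise the cause of these moves was not tested. The surrogate variable followed the GC trend (absolute r = 0.901). Leaving out each library gave 100 to 179 higher and 104 to 294 lower genes for strain, lowest without C3H replicates 2 and 3 and highest without B6 control replicate 5, and 2 to 37 higher and 2 to 165 lower genes for MK801. By library, the lower strain genes were 152, 112, 104 and 142 without C3H replicates 1, 2, 3 and 4. The higher MK801 genes were 13 and 11 without B6 control replicates 3 and 7, and 6, 7, 2 and 37 without MK801 replicates 2, 3, 4 and 5. The lower ones were 30, 33 and 17 without B6 control replicates 1, 3 and 7, 35 without C3H replicate 3, and 2, 9, 2 and 165 without MK801 replicates 2, 3, 4 and 5. The lists called ranged from 5 to 8 and from 9 to 14 when each library was left out, and were 10 and 11 without the 3 libraries of steepest GC trend. With an estimated correlation 0 and 0 lists were called, with 1 and 6 at an unadjusted p under 0.05, and fry called 0 and 6. The correlation of strain and MK801 changes ranged from 0.0703 to 0.316 without each library, and was -0.0602 with the controls divided. Of the named genes past the threshold, 7 of 35 in the strain comparison (Dlgap1, Cish, H2-K2, Adamdec1, Folr1, Dynlt1a and H2-Ea-ps) and 0 of 23 after MK801 were called under every alternative. The 0 of 23 was fixed by the leukocyte covariate, under which edgeR called 0 genes after MK801, so the 2 shares cannot be compared. No named gene reversed its direction while called.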

Other observations

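The tests in this part were written before their results were seen, but both readings were made more cautious afterwards, since the rule as first coded took 1 criterion before the other and ignored the spread.

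A candidate explanation for the rise of Fkbp5, Fam107a and Cry2 after MK801, of which Cry2 lost its call whichever MK801 library was left out (edgeR adjusted p from 0.0568 to 0.121), is a glucocorticoid response, for instance to handling or injection, as the controls were untreated or given saline. A list of 20 glucocorticoid target genes that left these 3 out gave mixed evidence: its camera p with an estimated correlation was 0.0457, which met the criterion for the explanation, while its median log2 fold change of 0.11 (standard error of the mean over members 0.214) met the criterion against it. None of the 20 passed the test alone (edgeR adjusted p), with Zbtb16 at a log2 fold change of 3.39 (edgeR adjusted p = 0.0734) and Cdkn1a at 0.77 (edgeR adjusted p = 0.0602) the nearest, and Mt1 and Mt2 at -1.07 and -1.15. A difference in the time of day of sampling may also raise Cry2. Genes of the evening phase had a median log2 fold change of 0.286. Those of the morning phase, Arntl, Clock and Nfil3 alone, had one of -0.118. The difference of 0.404 met the criterion against this explanation, but by less than an error of 0.271. That error combines the standard errors of the 2 means over genes, so it is only a rough guide for medians. It treats genes as replicates and does not measure the spread between libraries. Both explanations stay open, as does an effect of MK801 itself.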
